A study of Mus musculus with 4 samples.

How the data were processed

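RNA from mouse embryonic stem cells was sequenced in 4 libraries, 1 for each combination of 2 cell lines (E14, strain 129P2/OlaHsd, and JB1, strain JF1/B6) and 2 genotypes (wild type and Zfp57-/-). Per the labels' protocols, the cells grew without feeder cells on gelatin in serum and leukemia inhibitory factor, RNA was extracted with TRI reagent, and libraries were made with a stranded Illumina TruSeq kit for poly(A)-selected mRNA. Groups were taken from the sample titles. The labels name no replicates within a line and genotype, so each group was 1 library.

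The deposited tables, 1 per line, hold log2 values of RPM, reads per 1000000 reads of a library total, for 26130 genes, with the position and symbol of each gene. Per the submitters' processing notes, CASAVA 1.8.2, cutadapt and TopHat2 2.0.8b were used with the genome build mm9. The gene annotation, the counting tool, its strand setting, its treatment of reads that map to several places, the unit that was counted (reads or read pairs) and the total behind the scaling are not given in the sources used here. The scale was read from the values themselves. In every library, 0.9 × 2^(value − lowest value) was a whole number for 100% of the genes above the lowest value, within a relative tolerance of 0.0001, so a gene without reads had been written as 0.9 of a read and whole reads could be recovered. The scaling divided by 50478922 reads for E14 wild type, 70691473 for the E14 knockout, 69204114 for JB1 wild type and 96996280 for the JB1 knockout. The reads in the listed genes made up 53.1%, 53.7%, 68.6% and 68.9% of these totals. The values are not corrected for gene length, so levels of different genes within a library are not compared here. The 13 mitochondrial genes in the tables had 0 reads in all 4 libraries, so mitochondrial reads appear not to have been counted and that share of the libraries was not analysed here. The last gene on chromosome 1 ended at position 197002909 in the tables, beyond the last gene end of 195323493 in the available GENCODE M21 annotation of GRCm38. All coordinates below are therefore those of the deposited tables (mm9), and the reference served only for gene symbols, older symbols and transcript GC content. Exon, intron and UTR positions were not used.

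From the deposited values, RPM were computed as 2 to the power of the value, with 0 for genes without reads. Differences within a line were log2((knockout RPM + 1)/(wild-type RPM + 1)). This scale understates the change of genes near or below 1 RPM. Ratios given as fold are ratios of RPM without the added 1. Their 95% intervals are exact conditional binomial (Clopper-Pearson) intervals on the recovered reads. They cover counting error only, not the spread between cultures, and reads without molecular identifiers are not independent molecules. At 1 RPM a gene had 50.5 reads in the shallowest library and 97.0 in the deepest. A count of 0 allowed up to 0.0594 RPM in E14 wild type and up to 0.0309 RPM in the JB1 knockout, taking 3 reads as the limit. The 2 tables were kept apart, and every difference was formed within its own table.

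Within a line no test was possible. Genes with at least 1 RPM in either library were counted when they differed at least 2-fold on the log2(RPM + 1) scale. The effect shared by both lines was tested with limma 3.58.1 in R 4.3.3 on log2(RPM + 1), with cell line and genotype as terms, eBayes with a mean-variance trend, genes at a mean of at least 1 RPM, and Benjamini-Hochberg adjusted p under 0.05. The 2 lines are the only replication of the genotype, which leaves 1 residual degree of freedom per gene. The p-values and standard errors (SE) rest on how far the lines disagreed about the knockout difference. This disagreement was moderated by eBayes towards the trend over all genes, with 5.28 prior degrees of freedom. The SE of a single gene can therefore be smaller than the disagreement of its own 2 lines would give. The design fixed before the data were examined had foreseen a count model for count tables and limma for normalized values. Because the deposited values are log2 values, limma was used, and the alternatives that apply only to count tables (other size factors and a second count model) were not run.

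Gene lists were also fixed before the data were examined. They were imprinted genes whose active copy lies on the chromosome with the unmethylated germline control region (imprinted, unmethylated side), imprinted genes active on the other copy (imprinted, methylated side), naive pluripotency, primed pluripotency, primitive endoderm, mesoderm, neuroectoderm, trophoblast, the 2-cell-like state, fibroblasts or feeder cells, germline genes silenced by DNA methylation, DNA methylation and KAP1 corepressor machinery, p53 and stress, immediate early and heat shock genes, hypoxia and glycolysis, cell cycle, extracellular matrix and adhesion, Y-linked genes with Xist and Tsix, Zfp57 and its neighbours, clustered protocadherins, X-linked Rhox, Xlr and Mage genes, ribosomal proteins, mitochondrial genes and replication-dependent histones, 24 lists in all. Of 343 symbols written out, 327 matched a symbol in the tables, 7 matched through an older symbol and 9 did not match. Where a symbol had several entries, the lists used only the entry with the highest mean RPM over all libraries. The entries used for Kcnq1ot1, Zrsr1 and Peg13 carry a transcript identifier. Some lists share genes: Peg10 stands in the imprinted and trophoblast lists, Dnmt3b in the primed pluripotency and DNA methylation lists, and Zfp57 itself in the list of its neighbours. Within each line, a list was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. Over both lines, lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry.

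The genes named below follow a rule fixed before the data were examined. It takes Zfp57, the 10 genes most increased and the 10 most decreased in each line on the log2(RPM + 1) scale at 1 RPM or more, the 10 per direction that passed the shared test with the same sign or, with fewer than 5 passing, the 10 with the largest smaller-of-both-lines difference, up to 4 members of each list with the largest mean absolute difference, and the members of both imprinted lists. Genes outside this rule are named as chosen after their values were seen. Histone, Xlr, Zscan4 and ribosomal protein genes have near-identical copies that can share reads, and genes that overlap or lie antisense to another gene (Tsix, Kcnq1ot1, Nespas, Copg2 beside Mest, Zrsr1 inside Commd1, Peg13 inside Trappc9, Hist2h3c1 beside Hist2h2aa1) can take its reads where strand was not used, so their values are uncertain.

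The procedures were tested on simulated data drawn from the library means and depths. With a simulated spread of 10% between libraries, the shared test found 100% of the 100 genes altered 2-fold and 100% of the 100 genes altered 4-fold among 12473 genes, with 12 false calls. With a spread of 30% it found 6% and 91% among 12447 genes, with 10 false calls. In each simulation all genes had the same spread, and an altered gene had the same fold in both lines. The real lines need not share either, so these percentages do not carry over to the data. Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter, a filter of 5 RPM, median-ratio scaling, a 3-fold threshold, no cell line term, means in place of list medians, an estimated correlation and fry. Added after seeing the data were voom on the recovered reads, scaling to the reads in listed genes, fits without 3 chromosome regions or without histone genes, list tests of the neighbours without Zfp57 and of histone genes at 1 RPM in a library of each line, list medians over genes at 1 RPM in both lines, and list tests with 2-, 4- or 16-fold added to each list that camera called. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.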

Results

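The series asked how mRNA levels in mouse embryonic stem cells without ZFP57, a KRAB zinc finger protein that binds methylated imprinting control regions, differed from those of wild-type cells. The comparison was made in 2 lines, E14 (strain 129P2/OlaHsd) and JB1 (a cross of the strains JF1 and B6), with 1 library per line and genotype. The listed genes held 26801865 reads in E14 wild type, 37965626 in the E14 knockout, 47458221 in JB1 wild type and 66849394 in the JB1 knockout. With no replicates within a line, intervals on the fold values below cover counting error only, and no p-value is given for a single line.

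Zfp57 (chromosome 17, 37138108 to 37147580, plus strand, mm9) was lower in both knockout libraries. Its level was 135 RPM in E14 wild type and 51.8 RPM in the E14 knockout, 2.60-fold lower (95% interval 2.502 to 2.712). In JB1 it was 796 RPM in the wild type and 42.9 RPM in the knockout, 18.5-fold lower (95% interval 17.97 to 19.14). Both directions matched the genotype labels. The labels do not say which part of the gene was deleted, and the values are per gene, so the reads left in the knockout libraries could not be placed inside or outside the deletion. The gene's neighbours were not all alike. H2-M5, a histocompatibility gene (37121006 to 37126482), was 36.4 and 31.0 RPM in E14 wild type and knockout and 50.3 and 10.2 RPM in JB1, 4.93-fold lower (95% interval 4.59 to 5.29). Gabbr1, a GABA-B receptor subunit, differed little in E14 (24.5 and 23.1 RPM) and was 1.82-fold lower in JB1. Ubd, a ubiquitin-like modifier, had 0 reads in both E14 libraries (which allows up to 0.0594 RPM in the wild type) and was 0.954 RPM in JB1 wild type and 4.36 RPM in the knockout. The median of a list holding Zfp57 itself and its neighbours was −0.23 over 3 measured genes in E14 (percentile 6.11 of matched random lists) and −0.85 over 5 in JB1 (percentile 0.05). With the mean in place of the median, the E14 value was −0.56 (percentile 0.11).

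Imprinted genes of the unmethylated side, those active on the chromosome whose control region lacks methylation, were mostly higher in the knockout libraries of both lines. In JB1, 19 of 25 measured members were higher, 10 of them at least 2-fold, and none was at least 2-fold lower. In E14, 22 of 23 were higher, 2 of them at least 2-fold (Plagl1 and Peg13). These counts are on the log2(RPM + 1) scale. The list median was 0.46 on the log2 scale in JB1 and 0.39 in E14, and both lay at percentile 100 of the matched random lists. The 3 noncoding transcripts of the Dlk1-Dio3 cluster on chromosome 12 were among the 4 genes with the highest log2 ratio in JB1. Rian (110842155 to 110899919) was 57.7 RPM in JB1 wild type and 633 RPM in the knockout, 10.96-fold higher (95% interval 10.6 to 11.3). Meg3 (110779211 to 110809936) was 56.8 and 459 RPM, 8.09-fold higher (95% interval 7.83 to 8.36), and Mirg (110973191 to 110987665) was 3.80 and 32.2 RPM, 8.46-fold higher (95% interval 7.46 to 9.64). In E14 the same transcripts were 1.34-, 1.44- and 1.41-fold higher.

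Other members were also at least 2-fold higher in JB1. Peg10, a retrotransposon-derived gene on chromosome 6, was 4.57-fold higher (97.3 and 445 RPM). H19, a noncoding RNA on chromosome 7, was 3.48-fold higher (53.5 and 186 RPM), Snrpn 2.15-fold (119 and 255 RPM), Peg3 2.37-fold (128 and 302 RPM) and Mest 2.11-fold (43.8 and 92.5 RPM). Nnat was 7.74-fold higher at a low level (0.564 and 4.36 RPM), and Usp29 was 3.57-fold higher (1.503 and 5.36 RPM). In E14, H19 was 1.99-fold higher (9.91 and 19.7 RPM), Snrpn 1.804-fold (70.2 and 127 RPM), Nnat 2.95-fold (0.872 and 2.57 RPM), Peg3 1.32-fold, Peg10 1.27-fold and Mest 1.09-fold. Peg10, Mest and Sgce lie on chromosome 6, whose genes as a whole were lower in the E14 knockout library, with a median of −0.31. Plagl1, a zinc finger gene, and Peg13 went in opposite directions in the lines. Plagl1 was 3.29 and 10.9 RPM in E14 wild type and knockout and 27.8 and 16.0 RPM in JB1. Peg13 was 1.13 and 5.62 RPM in E14 and 11.1 and 7.41 RPM in JB1. Mkrn3 was lower in both lines (1.498- and 1.52-fold). Impact was 1.15-fold higher in E14 and 1.01-fold lower in JB1, Kcnq1ot1 was 1.22- and 1.04-fold higher, and Zrsr1 was 1.24-fold higher in E14 and 1.06-fold lower in JB1. Peg13 lies inside Trappc9, and strand was not known to be used, so its reads are uncertain.

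Imprinted genes of the methylated side included the steepest difference of the list pair. Grb10, which encodes a growth factor receptor adaptor (chromosome 11, 11830511 to 11938686), was 220 RPM in JB1 wild type and 12.0 RPM in the knockout, 18.3-fold lower (95% interval 17.2 to 19.4). In E14 it was 323 and 200 RPM, 1.62-fold lower (95% interval 1.58 to 1.66). Igf2r, the receptor that clears IGF2, was 239 and 120 RPM in JB1, 2.00-fold lower, and 221 and 268 RPM in E14, 1.21-fold higher. Trappc9 was 1.96-fold lower in JB1 and 1.26-fold lower in E14. Dlk1 and Asb4 were at least 2-fold higher in JB1 (1.33 and 5.47 RPM, and 0.159 and 1.51 RPM). The list as a whole went both ways, with 14 of 24 measured members lower in JB1 and 10 of 18 in E14, and its medians (−0.04 in each line) lay inside the range of random lists, at percentiles 19.06 and 13.6. In JB1 the list lay below that range with a filter of 5 RPM (median −0.27, percentile 1.22) and with the mean in place of the median (−0.19, percentile 0.64).

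**Figure D1:**
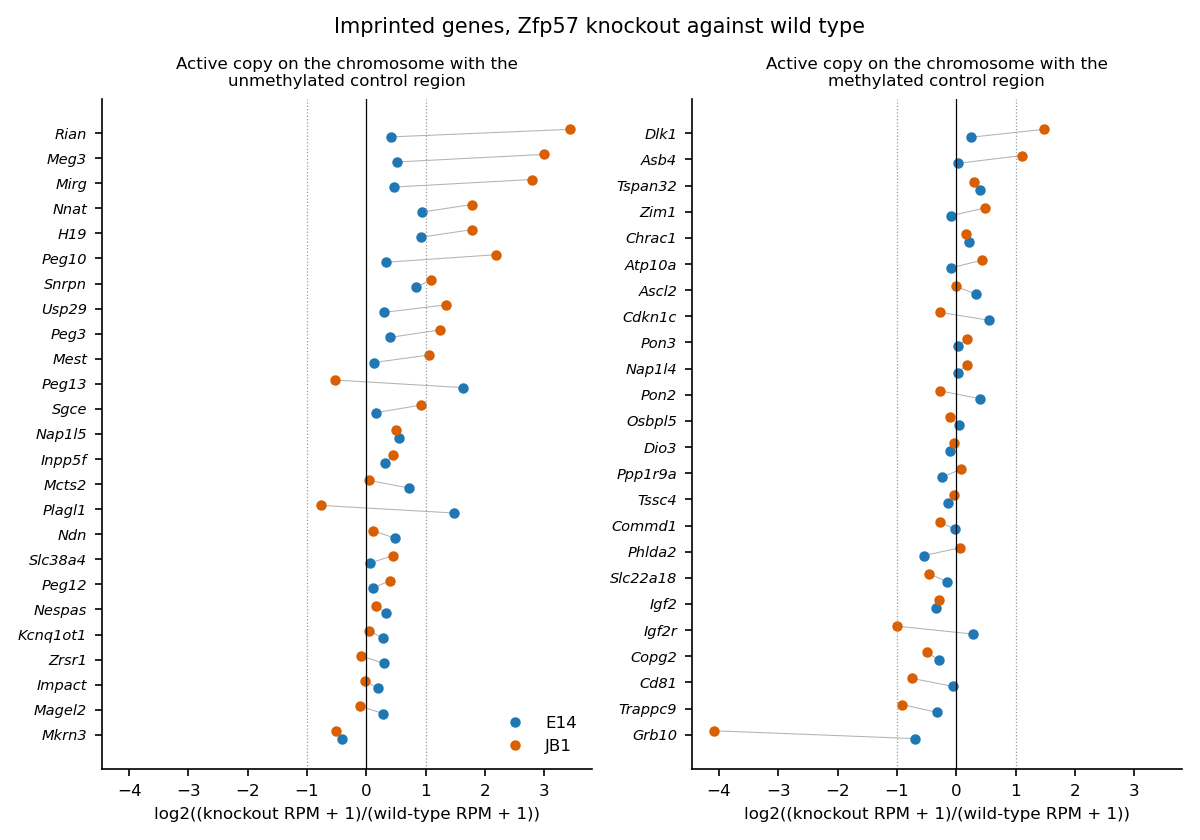
Each point gives, on the horizontal axis, the log2 ratio of (knockout RPM + 1) to (wild-type RPM + 1) of an imprinted gene in E14 (blue) or JB1 (orange), 1 library per genotype and line, with dotted lines at 2-fold and a panel each for the unmethylated and the methylated side. Rian, Meg3 and Mirg reach 3.43, 2.99 and 2.79 in JB1 and 0.42, 0.52 and 0.47 in E14, and Grb10 lies at −4.08 in JB1 and −0.69 in E14.

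In E14, the genes that stood highest in the knockout library were replication-dependent histone genes, which package newly made DNA. All 65 measured histone genes were higher and 54 were at least 2-fold higher, with a median of 1.55 on the log2 scale, at percentile 100 of random lists. Summed over 67 histone genes, the level was 935 RPM in the wild type and 2499 RPM in the knockout. Hist1h4c was 11.3 and 85.7 RPM, 7.57-fold higher (95% interval 6.95 to 8.27), and 9 of the 10 genes with the highest log2 ratio were histone genes, among them Hist2h2aa2, Hist1h4h, Hist1h4a and Hist1h4d, between 5.00- and 6.74-fold higher. Transcripts of these genes lack a poly(A) tail, and the libraries were poly(A)-selected. The gene at the head of the order was Dcdc2a, a doublecortin-domain gene on chromosome 13 (25147873 to 25302575), at 0.475 RPM in the wild type and 19.99 RPM in the knockout, 42.0-fold higher (95% interval 28.1 to 65.8).

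X-linked Rhox, Xlr and Mage genes, families expressed in germ cells and placenta, were also higher in the E14 knockout library. Of 15 measured members, 13 were higher, 10 of them at least 2-fold, and the median was 1.21 (percentile 100). The 10 Xlr genes summed to 17.9 RPM in the wild type and 58.1 RPM in the knockout, with Xlr4a 4.205-fold and Xlr5b 4.213-fold higher. Near-identical copies of these genes and of histone genes can share reads. Of 22 germline genes whose promoters are known to be silenced by methylation, 20 were higher, with a median of 0.51 (percentile 100) and no member beyond 2-fold. Among them were Taf7l (13.3 and 25.2 RPM) and Stk31 (14.4 and 23.9 RPM), the latter on chromosome 6, whose genes had a median of −0.31. All 9 measured genes of the 2-cell-like state were higher, with a median of 0.50 (percentile 99.9), such as Zscan4c (6.28 and 8.98 RPM). Primed pluripotency genes lay higher (median 0.42, percentile 99.95), with Dnmt3b at 47.7 and 67.2 RPM, as did immediate early and heat shock genes (0.32, percentile 99.95), hypoxia and glycolysis genes (0.31, percentile 100) and ribosomal protein genes (0.13, percentile 100). The hypoxia and glycolysis list lay inside the random range with the mean in place of the median (0.13, percentile 95.2).

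Fewer genes were lower in E14. Naive pluripotency genes had a median of −0.11 (percentile 0.35), with 14 of 22 lower. Nanog, a core pluripotency factor, was 228 and 137 RPM, 1.67-fold lower, and Prdm14, a repressor of primed genes, was 16.9 and 7.94 RPM, 2.13-fold lower (95% interval 1.92 to 2.38). Klf4 was 1.09-fold lower. Besides Zfp57, the genes with the lowest log2 ratios were Gm10801, Gm16869, the cadherin Fat2, the activin subunit Inhbb (19.3 and 6.31 RPM), Adamts3, Nkx6-3, Epb4.9, Tdh, which degrades threonine (116 and 46.6 RPM), and the guidance cue Ntn1 (15.1 and 5.90 RPM). The primitive endoderm median of −0.13 (percentile 2.37) turned to 0.01 (percentile 44.8) with a filter of 5 RPM, and it lay inside the random range with a pseudocount of 5 (percentile 5.53), with the mean in place of the median (percentile 5.09) and without the chromosome 6 and 14 regions below (percentile 10.1).

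Many of the lower genes of the E14 knockout library lay together on chromosome 14. Between 41 and 77 Mb, 147 of 154 genes with a mean of at least 5 RPM were lower, with a median of −0.70 (95% bootstrap interval over genes −0.75 to −0.68), against 0.03 elsewhere. The region held 16 of the 33 genes at least 2-fold lower, Tdh and Epb4.9 included, and 1.88% of the measured genes. Over the whole of chromosome 6, on which Nanog lies, 359 of 409 genes were lower, with a median of −0.31 (−0.35 to −0.29). The same regions had medians of −0.02 and −0.00 in JB1. In JB1, genes of chromosome 1 beyond 140 Mb were lower instead, 161 of 197, with a median of −0.34 (−0.39 to −0.29), against −0.01 for these genes in E14. These regions were chosen after the values were seen. When genes were permuted over the genome 1000 times, 95% of the permutations had no window of 10 Mb farther than 0.27 from the E14 median. In the data, 15 of 237 windows lay below this limit, all on chromosomes 6 and 14, and 1 lay above, with the histone genes of chromosome 13. In JB1 the limit was 0.43, and 1 of 241 windows, on chromosome 1, passed it.

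**Figure D2:**
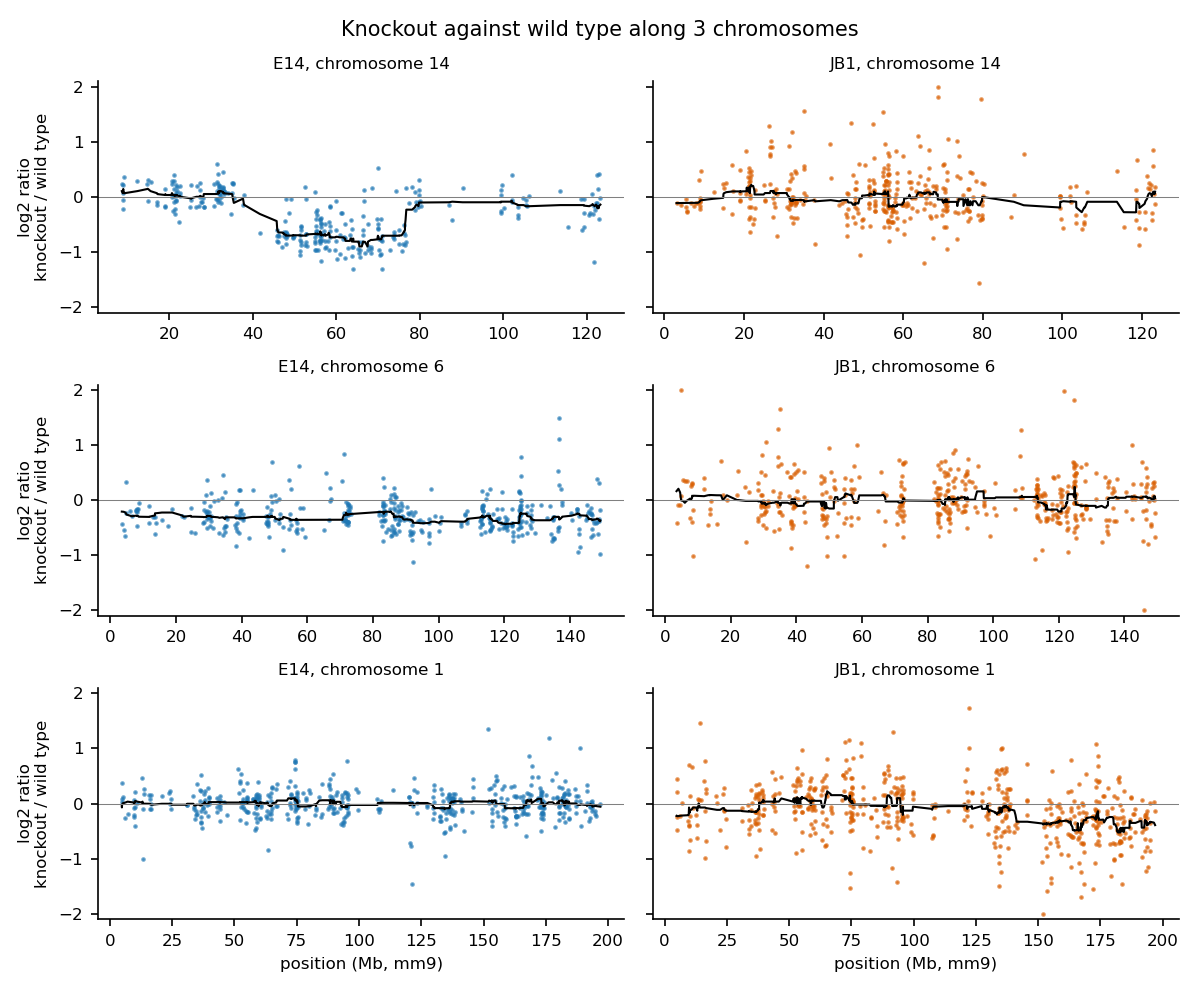
Log2 ratio of knockout to wild type for each gene with a mean of at least 5 RPM (points, drawn at 2 or −2 where they lie beyond) against its mm9 position in Mb, with a running median of 31 genes (black), for chromosomes 14, 6 and 1 in E14 (left) and JB1 (right). The E14 line falls to about −0.70 between 41 and 77 Mb of chromosome 14 and lies near −0.31 along chromosome 6, and the JB1 line lies near −0.34 beyond 140 Mb of chromosome 1.

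In all, 117 of 12276 genes at 1 RPM or more were at least 2-fold higher in the E14 knockout library and 33 were at least 2-fold lower. Without histone genes 63 were higher, and without the chromosome 6 and 14 regions 16 were lower. The median difference over all genes was 0.02. The difference has no replicate check. With a pseudocount of 5, 44 genes were higher and 6 lower.

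In JB1, genes of glycolysis and the hypoxia response stood out as higher in the knockout library. Of 19 measured members 15 were higher, 12 of them at least 2-fold, with a median of 1.06 (percentile 100). Ldha, which makes lactate (chromosome 7, 54096845 to 54110997), was 88.4 RPM in the wild type and 585 RPM in the knockout, 6.62-fold higher (95% interval 6.45 to 6.80). Eno1 was 3.49-fold, Pdk1 3.74-fold and Pgk1 3.15-fold higher. Cell cycle genes were higher by a smaller margin (median 0.28, percentile 99.9, 18 of 20 higher), led by the cyclins Ccnd3 (82.8 and 273 RPM) and Ccne1 (33.6 and 97.7 RPM). Primitive endoderm genes were higher in 14 of 15 cases, with a median of 0.50 (percentile 99.95). The named members were at low levels, Cubn at 2.43 and 8.89 RPM and Hnf4a at 0.405 and 2.09 RPM, apart from Sparc (190.0 and 307 RPM), and Gata4 was lower (6.10 and 2.97 RPM). The trophoblast median was 0.62 over 7 genes (percentile 99.6), with Peg10 and the keratin Krt8 (5.79 and 13.96 RPM) at least 2-fold higher.

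Stress and early response genes were lower in the JB1 knockout library. Of 17 genes of the p53 and stress list 14 were lower, with a median of −0.66 (percentile 0) and no member beyond 2-fold; Cdkn1a, the p21 cell cycle inhibitor, was 63.2 and 31.6 RPM. Of 14 immediate early and heat shock genes 12 were lower, 4 of them at least 2-fold, with a median of −0.41 (percentile 0). Fos was 46.1 and 4.72 RPM, 9.77-fold lower (95% interval 8.85 to 10.8), Egr1 was 166 and 30.5 RPM, 5.45-fold lower, and Fosb was 14.1-fold lower (5.97 and 0.423 RPM). Germline genes were lower in 17 of 23 cases (median −0.31, percentile 0.05), with Taf7l 5.08-fold and Tdrd9 5.91-fold lower, while Stra8, which licenses entry into meiosis, was 4.18-fold higher. Rhox, Xlr and Mage genes had a median of −0.27 (percentile 0.72), which lay inside the random range with the mean in place of the median (−0.20, percentile 2.70). The 6 histone genes at 1 RPM had a median of −0.49 (percentile 0.46), and all histone genes summed to 39.6 RPM in the wild type and 28.0 RPM in the knockout. The 3 measured protocadherins had a median of −0.75 (percentile 0.24), which a pseudocount of 5 moved to −0.22 (percentile 2.58).

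Naive pluripotency genes were lower in the JB1 knockout library in 17 of 22 cases, with a median of −0.21 (percentile 1.8). Klf4 was 410 and 164 RPM, 2.497-fold lower (95% interval 2.45 to 2.55), and Nanog was 693 and 362 RPM, 1.91-fold lower, whereas Utf1 was 2.77-fold higher. The DNA methylation and KAP1 list went both ways and stayed inside the random range, with a median of −0.06 (percentile 39.0) in JB1 and 0.06 (percentile 76.1) in E14. Of its 17 genes, 3 were beyond 2-fold in JB1. The de novo methyltransferases Dnmt3a and Dnmt3b were 4.27-fold (19.9 and 84.9 RPM) and 2.37-fold (61.4 and 145 RPM) higher, and Tet2, which oxidizes methylcytosine, was 2.38-fold lower (563 and 237 RPM).

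Beyond the lists above, the genes with the highest log2 ratios in JB1 were the neurofilament gene Nefm (2.56 and 34.2 RPM, 13.4-fold), the kinase Fgr (0.361 and 7.08 RPM), 1110002J07Rik, the lectin Clec4a1 and the cyclooxygenase Ptgs1 (2.01 and 13.9 RPM). The intermediate filament Vim (7.05 and 37.4 RPM), a member of the extracellular matrix and adhesion list, was also among the highest. The lowest ratios after Zfp57 and Grb10 were those of the forkhead gene Foxd1 (19.6 and 1.32 RPM, 14.8-fold), P2rx3, Hhip, an inhibitor of hedgehog signalling (13.6 and 1.10 RPM, 12.3-fold), Itpr2, Ptgs2 and Kcnt2, the last 2 in the distal chromosome 1 region. In all, 328 of 13132 genes were at least 2-fold higher and 208 at least 2-fold lower, with a median difference of 0.01 and no replicate check. Of the 208 lower genes, 20 lay in the distal chromosome 1 region, which held 1.87% of the measured genes. A pseudocount of 5 left 111 and 83.

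The remaining lists stayed inside the range of random lists in both lines. Neuroectoderm genes (medians 0.10 in E14 and 0.10 in JB1, with Tubb3 at 33.1 and 45.9 RPM in E14), fibroblast or feeder genes (0.05 and 0.41, with Fn1 at 883 and 1271 RPM in JB1), and extracellular matrix and adhesion genes (0.15 and −0.10) did not stand apart, although Lamc1, a laminin subunit in the distal chromosome 1 region, was 1282 and 501 RPM in JB1 and 364 and 513 RPM in E14. Vim, of the same list as Lamc1, was among the most increased genes in JB1. The extracellular matrix median in E14 lay at percentile 97.45 and passed beyond the random range with a pseudocount of 5 (percentile 99.04) and with the mean in place of the median (percentile 99.2). The mean had the opposite sign to the median for extracellular matrix genes in JB1 (0.12), DNA methylation genes in JB1 (0.09), and fibroblast (−0.02), mesoderm (−0.19) and neuroectoderm genes (−0.03) in E14. Of the mesoderm list 3 genes were measured in E14 (median 0.02) and 2 in JB1, among them Bmp4, in the chromosome 14 region, at 10.1 and 4.95 RPM in E14 and 18.5 and 48.7 RPM in JB1. The p53 and stress list in E14 (0.13, percentile 97.1), primed pluripotency in JB1 (0.26, percentile 92.0), trophoblast in E14 (0.24, percentile 91.7), cell cycle in E14 (0.02, percentile 48.9), the 2-cell-like state in JB1 (0.49, percentile 96.3) and ribosomal protein genes in JB1 (−0.09, percentile 5.63) also lay inside. The p53 list in E14 passed the limit with a pseudocount of 5 (percentile 97.88) and without the chromosome 6 and 14 regions (percentile 97.83), and the 2-cell-like list in JB1 did with a pseudocount of 0.1 (percentile 97.97). The Y-linked genes Ddx3y and Eif2s3y were present at 52.7 RPM or more in all 4 libraries, and the list had medians of 0.02 and −0.27 (percentiles 53.7 and 4.17, the latter 2.22 with a pseudocount of 5). In all, 1 protocadherin was measured in E14, and no mitochondrial gene had a read.

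**Figure D3:**
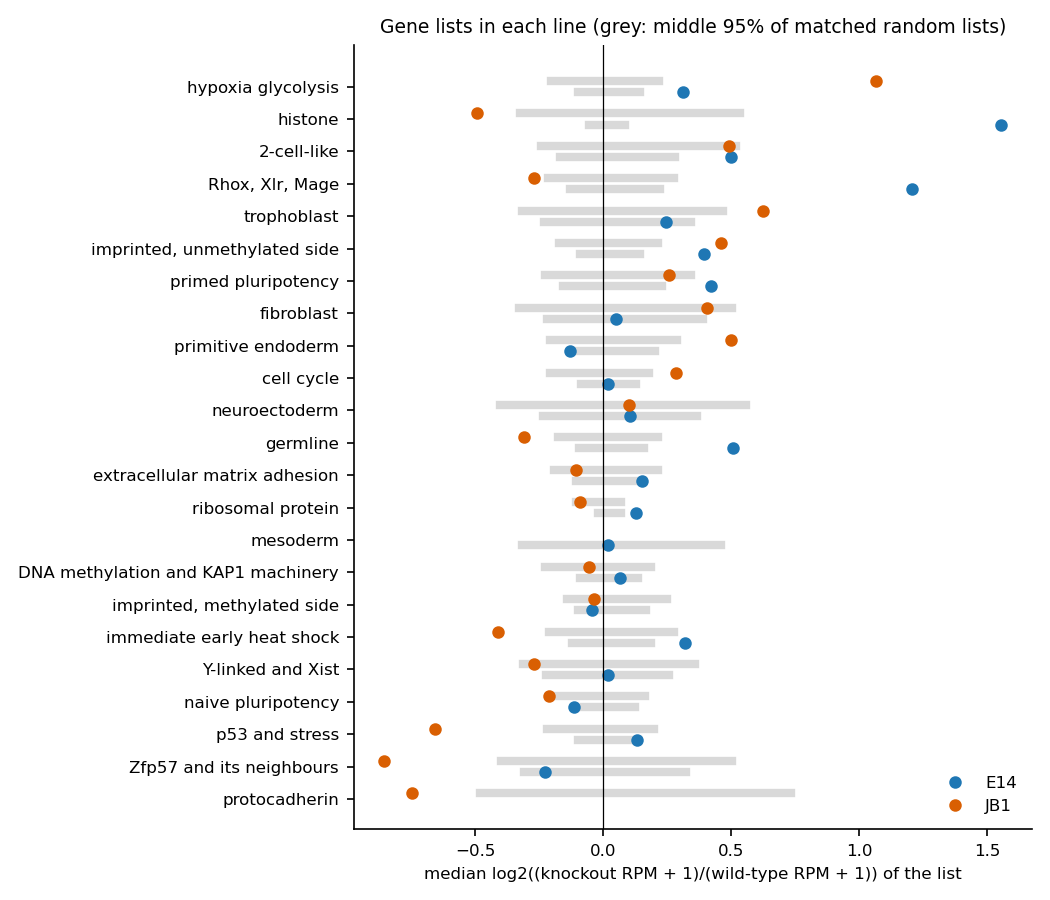
Median log2 ratio of (knockout RPM + 1) to (wild-type RPM + 1) of each gene list in E14 and JB1 (points), with the middle 95% of 10000 random lists matched on expression (grey bars), 1 library per genotype and line. Histone genes lie at 1.55 in E14 (65 genes) and −0.49 in JB1 (6 genes), hypoxia and glycolysis genes at 0.31 and 1.06, and imprinted genes of the unmethylated side at 0.39 and 0.46.

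Across both lines, no single gene passed the test of a shared genotype effect. With limma, 0 of 12644 genes had an adjusted p under 0.05, and the lowest adjusted p was 0.623. Zfp57 itself, 2.60-fold lower in E14 and 18.5-fold lower in JB1, was not called either. The count of 0 therefore does not show that shared effects were absent. At an unadjusted p under 0.05 there were 1005 genes, 633 higher and 372 lower, where 632 would be given by chance. This count was 16 with no cell line term, 1408 with no filter (1306.5 by chance among 26130 genes) and 799 to 1080 with the other alternatives in limma. With voom on the recovered reads there were also 0 genes (lowest adjusted p 0.488, 1262 at an unadjusted p under 0.05). The genes that differed most in the same direction in both lines were Rpl39l, a ribosomal protein paralog (chromosome 16, 10170319 to 10175004), which was 4.38-fold higher in E14 (5.96 and 26.1 RPM) and 2.57-fold higher in JB1 (18.5 and 47.7 RPM), the bone morphogenetic protein target Id1 (3.61- and 2.53-fold), BC051077 (2.29- and 2.15-fold), the lactate transporter Slc16a3 (2.43- and 3.51-fold) and Fam25c (2.41- and 3.55-fold). Gsta3, Col5a3, Lama3, Prss50 and Nnat followed. In the other direction, Zfp57 was followed by Tmem81 (2.20- and 3.08-fold lower), Epb4.9, the hedgehog receptor Ptch1 (1.87- and 3.03-fold lower), 6720456H20Rik, Itga9, Ano9, Pnma2, Nanog and the retinoblastoma gene Rb1 (1.71- and 1.74-fold lower). Epb4.9, 6720456H20Rik, Pnma2 and Rb1 lie in the chromosome 14 region and Nanog on chromosome 6.

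At the level of lists, imprinted genes of the unmethylated side were higher in the mean of both lines, with 23 of 24 members higher and a median of 0.53. Member counts in this paragraph go by the sign of a gene's mean difference over the lines, so they do not show that the lines agreed. Within the lines, 22 of 23 measured members of this list were higher in E14 and 19 of 25 in JB1. Camera called this list as higher, with an adjusted p of 2.1e-08. This call was lost with an estimated correlation (adjusted p = 0.885 with an estimated correlation) and with fry (adjusted p 0.438). Adjusted over the list alone, limma called 3 members, H19 (1.35 ± 0.23, SE, adjusted p 0.0103), Snrpn (0.97 ± 0.16, adjusted p 0.0103) and Nnat (1.36 ± 0.28, adjusted p 0.0193), all of which rose, and 0 over all genes. The count over the list alone was 0 with no cell line term and 6 without the 3 chromosome regions. Camera also called the lists of histones (adjusted p 2.5e-15, 62 of 63 higher), the 2-cell-like state (2.9e-04, 8 of 8 higher), hypoxia and glycolysis (5.3e-04, 14 of 19 higher), Rhox, Xlr and Mage genes (0.0056), cell cycle (0.0141, 17 of 20 higher) and trophoblast (0.0341) as higher, and naive pluripotency (0.0021, 16 of 22 lower), p53 and stress (0.0318, 13 of 17 lower) and Zfp57 with its neighbours (0.0318, 3 of 4 lower) as lower. None of these calls held with an estimated correlation (adjusted p = 0.885 with an estimated correlation for each of the 10 lists) or with fry (adjusted p 0.438 or above). With 1 residual degree of freedom these tests had little room to call a list. When 16-fold was added to every member of each of the 10 lists in both knockout libraries, either test still called 0 (lowest adjusted p 0.647 and 0.0775). The losses therefore do not count against the lists, and the camera calls rest on an assumed correlation of 0.01. The neighbour list holds the knocked-out gene, and without Zfp57 its 3 other genes were not called (adjusted p 0.306). Most histone genes were below 1 RPM in JB1, and the 5 tested histone genes that reached 1 RPM in a library of each line were not called (adjusted p 0.276). The added change and the tests of these 2 smaller lists were chosen after seeing the data. Without the 3 chromosome regions, also chosen after seeing the data, Peg10 on chromosome 6 left the trophoblast list. Its 5 other genes were not called by camera (adjusted p 0.165). Several of the called lists had medians of opposite sign in the lines, as given above for histones and for Rhox, Xlr and Mage genes. The same holds for the p53 and stress list, whose E14 median lay inside the random range. Of the 17 p53 and stress genes 12 were higher in E14, and of the 20 cell cycle genes 10 were. In the glycolysis list 11 members were called when adjusted over the list alone, and 0 with median-ratio scaling or with no cell line term. Of the 11, 9 rose, led by Ldha (1.64 ± 0.45, SE), and the glucose transporter gene Slc2a3 (chromosome 6) and the oxidoreductase gene Ero1l (chromosome 14) fell (−0.54 ± 0.19 and −0.75 ± 0.15), both in the regions that were lower in E14. Slc2a3 and Ero1l were singled out after their values were seen. Adjusted over the list alone, Nanog (−0.83 ± 0.17) and Prdm14 (−0.81 ± 0.18) in the naive list and Zfp57 (−2.77 ± 0.58) in its own list fell, and Rpl39l (1.64 ± 0.21) among ribosomal proteins rose. The naive and ribosomal calls were lost with median-ratio scaling and with no cell line term (0 each), and that of Zfp57 with no cell line term. Without the 3 chromosome regions 1 naive gene was called. Over all genes each of these lists had 0 calls.

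The other lists were not called by camera over both lines, and the mesoderm, protocadherin and mitochondrial lists were not tested there. Primitive endoderm (adjusted p 0.115), primed pluripotency (0.146), the methylated imprinted side (0.188), fibroblast genes (0.311), Y-linked genes with Xist and Tsix (0.311), immediate early and heat shock genes (0.382), ribosomal proteins (0.532), extracellular matrix (0.532), germline genes (0.568), neuroectoderm (0.936) and DNA methylation machinery (0.936) were tested. Neuroectoderm genes had a median of −0.17 and a mean of −0.02, and fry gave the opposite direction.

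The differences in the 2 lines were weakly related across genes. Over 11890 genes at 1 RPM or more in a library of each line, Pearson's r across genes was 0.17 (95% bootstrap interval over genes 0.15 to 0.19) and Spearman's rho was 0.21, and 58.0% of genes had the same sign. Genes are not independent replicates, and the lines shared no library. Of the genes at least 2-fold higher, 57 in E14 and 258 in JB1, 5 were shared (Rpl39l, Id1, BC051077, Slc16a3 and Fam25c), where independent lists would share 1.24. Of those at least 2-fold lower, 28 and 192, Zfp57 alone was shared, where independent lists would share 0.452. In opposite directions, 4 genes were at least 2-fold higher in E14 and lower in JB1 (Ptgs2, Atf5, Id2 and Hist1h1c), and 2 were lower in E14 and higher in JB1 (Ntn1 and Adam19). Of these, Atf5, Id2, Hist1h1c and Adam19 were chosen after their values were seen. With 1 library per line and genotype, the difference between the lines could not be tested.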

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

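The genes and lists first given here went in opposite directions in the lines, while the imprinted genes at the end went mostly the same way, with more of them at least 2-fold higher in JB1. With 1 library per line and genotype, none of these differences between the lines was tested. All tests of explanations in this part were chosen, or had their criteria changed, only after the result was seen: the limit of the test on doubling was raised from 2-fold to 4-fold, its count was changed from genes to clusters, it was divided into 2 tests with a limit each, and the criterion of the test on a wider spread was made stricter, once their values were known. For genes, the values are log2 ratios of knockout to wild type at least 2-fold in each line. Ptgs2, an inducible cyclooxygenase, was 1.36 in E14 and −2.59 in JB1, a difference (JB1 minus E14) of −3.95. The differences were −2.72 for Id2 (1.12 and −1.59), −2.62 for the stress factor Atf5 (1.00 and −1.61), −2.101 for Hist1h1c (1.02 and −1.08), 2.69 for the protease gene Adam19 (−1.12 and 1.57) and 2.61 for Ntn1 (−1.22 and 1.38). Atf5, Id2, Hist1h1c and Adam19 were chosen after their values were seen. Ptgs2 lies in the distal chromosome 1 region that was lower in JB1.

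For lists, the medians lay beyond the random range on opposite sides. The difference of medians was −2.05 for histones (1.55 over 65 genes in E14 and −0.49 over 6 in JB1), −1.48 for Rhox, Xlr and Mage genes (1.21 and −0.27), −0.82 for germline genes (0.51 and −0.31), −0.73 for immediate early and heat shock genes (0.32 and −0.41) and 0.63 for primitive endoderm genes (−0.13 and 0.50). The histone medians are over unlike sets of genes. Over the 5 histone genes measured in both lines they were 1.21 and −0.66, and the 61 histone genes below 1 RPM in JB1 had a median of −0.02 there, with 25 higher and 34 lower. The E14 median of the primitive endoderm list depended on the settings, turning to 0.0062 with a filter of 5 RPM.

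Reads that moved between near-identical copies are argued against as the source of the histone difference in E14, since the sum over all histone genes was 2.67 times as high in the knockout library. A larger share of cells in S phase, when these genes are active, would also raise other S phase genes, and these had a median of 0.14 and none above 0.56 (Mcm2, Mcm3, Mcm5, Pcna, Ccna2, Ccne1 and Ccne2), against 1.55 for histones. How far such genes rise with that share was not tested, so these values do not measure it. A candidate explanation that stays open is that more RNA without a poly(A) tail was carried into that library. Other RNAs of this kind were searched only by symbols of mostly small noncoding RNAs, such as Snora, Snord, Scarna, Rmrp, Rpph1 and Terc genes. Of these, 0 reached 1 RPM in an E14 library, so nothing could be compared. Histone genes summed to 935 RPM in E14 wild type and 39.6 RPM in JB1 wild type, values from tables scaled separately. An effect of Zfp57 loss on histone transcripts in this line also stays open, untested.

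More imprinted genes of the unmethylated side were at least 2-fold higher in JB1 (10) than in E14 (2) on the log2(RPM + 1) scale. By the ratio of RPM without the added 1, Nnat (2.95-fold) and Nap1l5 (2.21-fold) also passed 2-fold in E14, and Sgce (2.27-fold) in JB1. Usp29, below 1 RPM in E14, was 2.68-fold higher there. Activation of the silent copy would at most double a transcript if 1 copy is fully active in the wild type and both copies give equal output. The tests of doubling take this as given, and it was not tested. In JB1, 10 genes from 7 of 17 clusters had a counting interval wholly above 2-fold, where the middle 95% of random lists matched on expression and clusters reached up to 3 clusters. These are the same 10 genes whose higher level prompted the test, and counting error leaves out the spread between cultures. The test therefore cannot decide on a doubling with only counting error beside it. A doubling with the spread of other genes on top cannot be told apart: 5 genes (Nnat, Peg10, Meg3, Rian and Mirg) from 3 clusters lay wholly above 4-fold, which a doubled gene passes where the gene itself passes 2-fold, and 3.81% of random lists had as many clusters. Counted as genes, the middle 95% of random lists reached up to 3, which the 5 genes passed. Meg3, Rian and Mirg belong to the same cluster, so the 5 are not independent. The wider spread of all differences in JB1 could account for the contrast between the lines: relative to matched genes, the list's median absolute difference in JB1 was 0.760 times that in E14, but the 95% bootstrap interval (0.533 to 1.93) leaves both outcomes possible. Functional Zfp57 transcript left in the E14 knockout is a further candidate explanation that cannot be told apart, because 51.8 RPM remained there and the deleted part is not known. A level of 42.9 RPM also remained in the JB1 knockout. The level left was 2.60-fold below the wild type in E14 and 18.5-fold below it in JB1. Strain, passage and the state of the wild-type imprints in each line also stay open, untested.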

How the results depend on the processing

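Scaling to reads in listed genes, voom and the fits without chromosome regions or histone genes, and lists with fewer members, were chosen after seeing the data. The shared test called 0 genes in each alternative (lowest adjusted p from 0.488 to 1.00), the 1005 genes at an unadjusted p under 0.05 became 16 with no cell line term, and leaving out a line left 1 library per group and no test. Alternatives for count tables only were not run. Counts of genes at least 2-fold different moved with the pseudocount. With a pseudocount of 0.1, E14 had 345 (268 higher, 77 lower) and JB1 1016 (656 and 360). With 5, E14 had 50 (44 and 6) and JB1 194 (111 and 83). At 3-fold they were 39 (38 and 1) and 108 (66 and 42), by the stricter threshold. Scaled to reads in listed genes, E14 had 230 (176 and 54). Without histone genes E14 had 96 (63 higher), and without the chromosome 6 and 14 regions 16 lower. No filter, 5 RPM and median-ratio scaling kept these counts within each line within 1.5 times. The correlation between the lines was 0.144 without a filter and 0.197 at 5 RPM. Genes 2-fold higher in both lines numbered 25 with a pseudocount of 0.1, 1 with 5 and 9 scaled to reads in listed genes; those lower numbered 5, 1 and 2. Among genes measured in both lines, those at least 2-fold higher in E14 (57) numbered 177 and 11 with pseudocounts of 0.1 and 5, 117 without a filter, 31 at 5 RPM and 110 scaled to listed genes, and those lower (28) 61, 5, 33, 24 and 45, and 11 without the chromosome regions. In JB1, those higher (258) numbered 401 and 107 with these pseudocounts and 157 at 5 RPM, and those lower (192) 284, 81 and 124. The 4 genes higher in E14 and lower in JB1 became 22 and 0 with these pseudocounts and 7 scaled to listed genes, and the 2 of the reverse kind 3, 0 and 2. Except where fewer genes or a stricter threshold entered, the cause was not tested. An estimated correlation and fry called 0 of the lists over both lines in place of 10 (and 0 with 16-fold added to each), while no cell line term and median-ratio scaling kept all 10 lists, but not the calls over the list alone: those in glycolysis went from 11 to 0 in both, in the naive list from 2 to 0 and in ribosomal proteins from 1 to 0, and with no cell line term those in the imprinted list from 3 to 0 and in the neighbour list from 1 to 0; without the 3 chromosome regions 9 were kept, trophoblast was lost and primed pluripotency and primitive endoderm were gained. The neighbour list without Zfp57 (adjusted p 0.306) and the histone genes at 1 RPM in both lines (0.276) lost their calls. Among lists within a line, the E14 primitive endoderm median reversed to 0.0062 at 5 RPM. With median-ratio scaling, all 22 list medians in each line kept their side. Of the named genes at least 2-fold different, 36 in E14 and 66 in JB1, none changed sign, and 17 and 47 stayed beyond 2-fold with a pseudocount of 5. The Zfp57 ratios of −1.36 and −4.18 moved by less than their counting error with median-ratio scaling and a pseudocount of 0.1. Depth limited genes near 1 RPM, with 50.5 reads in the shallowest library.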

Other observations

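The test of GC content in this part was fixed before its result was seen, and the tests of copies and of a shared regional effect were chosen after. Some gene groups had no place in the comparisons above. Hedgehog pathway genes appeared among the genes lower in the JB1 knockout under the naming rule, with Hhip 12.3-fold and Ptch1 3.03-fold lower, and Ptch1 was 1.87-fold lower in E14, where Hhip differed by 1.03-fold. This was noticed in the data, and no list of hedgehog genes was tested.

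Kdm5d, a Y-linked demethylase gene, had 0.0396 RPM in E14 wild type and 0.212 RPM in the E14 knockout, against 20.7 and 23.0 RPM in the JB1 libraries, while the Y-linked genes Ddx3y and Eif2s3y were at 82.2 RPM or more in both E14 libraries. The levels of the lines come from tables scaled separately.

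The lower block on chromosome 14 in the E14 knockout library may reflect fewer copies of the region than in the E14 wild-type cells. A ratio within the line cannot tell a loss in the knockout cells from a gain in the wild-type cells. Of the genes in the block 95.5% were lower. The medians of its genes of low, middle and high expression were −0.69, −0.77 and −0.70. The flanks of 10 Mb had medians of 0.10 and −0.07. The limits of the block were drawn from these same values. The share of lower genes and the unshifted flanks follow from that choice and cannot decide on copies. What the medians show is a shift that was alike at low, middle and high expression. A regional effect of Zfp57 loss in both lines is argued against by JB1, where the median of the same block was −0.024 (95% bootstrap interval −0.10 to 0.05). GC content is argued against as well, since genes elsewhere matched on GC content had a median of 0.0214 and no random draw of 10000 fell below −0.06. The data hold no DNA measurement, and a regional effect of Zfp57 loss in E14 alone stays open, untested.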
